A study of Mus musculus with 24 samples.

How the data were processed

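RNA from 24 cultures of mouse muscle cells was measured on Affymetrix whole-transcript gene arrays, 1 array per sample. The samples fall into 8 groups of 3 by genotype of the cell line, stage of culture and treatment, per the labels. Nothing in the labels says whether the 3 samples of a group were separate cultures or separate passages, so the p-values measure the spread between these samples, which may be partly technical.

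The deposited values are on a log2 scale, 1 value per probe set and array; the scale was read from the values, which run from 2.50 to 15.03. Affymetrix Expression Console and Partek are named in the submitters' processing notes without versions or roles, and the background correction, summarisation and normalization are not given in the sources used here. Array medians lay between 7.38 and 7.50 log2 units, so the arrays were already on a common scale, although their distributions were not identical. For arrays no count stands behind a value; the number of arrays limits the precision. The median within-group SD was 0.11 log2 units.

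The table has 35556 rows. The platform annotation lists 1 gene for 21789 rows, several genes for 1621 and no gene for 12146, and rows of the last 2 kinds were left out of the gene tests. Gene IDs of 21698 one-gene rows were found in the RefSeq table of assembly GRCm38.p6, and 0 symbols changed through them. For 999 genes with more than 1 row the row with the highest mean over the 24 arrays was kept, which left 19938 genes.

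A linear model with 1 mean per group was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3, leaving 16 residual degrees of freedom, and 13 contrasts were tested with moderated statistics. All adjusted p-values of genes are Benjamini-Hochberg values from limma over the 19938 genes, and a gene was called at an adjusted p under 0.05. Log2 changes are given with their standard errors (SE), and each contrast compares groups of 3 arrays. Differences between BMP4 responses were tested as interaction contrasts. The test was checked on simulated arrays with each gene's mean over all arrays, its real within-group spread and 200 changed genes among 19938. No other gene differed between groups, and the noise was independent, without the array set described below. With few changed genes the adjusted threshold is stricter, so the shares recovered hold for that setting and not for the real contrasts. For the BMP4 response in wild-type myoblasts it recovered 28% of the genes changed by 0.3 log2 units, 86% at 0.6 and 100% at 1. For the difference of responses in myotubes it recovered 8% at 0.3, 48% at 0.6 and 98% at 1.

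Before the data were examined, 27 gene lists with 594 genes were fixed, of which 549 genes were measured. The lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within a contrast, and again with an estimated correlation. The rule for named genes was fixed at the same time. It takes up to 10 largest rises and 10 largest falls among called genes whose arms do not overlap (called genes alone for interactions), up to 2 called members per list and direction, and always Musk, Id1, Id2, Id3, Smad6, Smad7, Rgs4, Car3, Wnt11, Myh15, Ptgs2 and Fabp7. The text uses fewer genes than the rule allows.

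Alternatives fixed beforehand were a fit on the compared groups alone, moderated statistics with trend and robust estimation, a filter on dim genes, quantile normalization, median centring, each row as its own test, replicate blocks, a fold change of at least 1.5, and leaving out each array in turn. In 4 myoblast arrays, 1 in each myoblast group, the rows without a gene name deviated together, and the correlations of their deviations over the genes tested ran from 0.42 to 0.54. These arrays are called the array set below. Among 3 groups, untreated wild-type, untreated MuSK-null and treated MuSK-null myoblasts, every pair of arrays with the same replicate number had a correlation of deviations above 0.1 (0.12 to 0.52), and 3 of the 4 arrays of the set carry the same number there. For the 2 contrasts between these groups the numbers pair the samples by that measure, although no label gives a shared batch or day. Over all groups they do not. Deviations within a group sum to 0, so arrays outside the set deviate together in the other direction. The pairing can therefore not be told apart from membership in the set. A fit with the set as a block and a fit without the set were added after seeing the data. The set holds 1 array of each myoblast group and was picked from deviations of these same arrays. As a block it leaves the log2 changes within myoblasts and the differences of BMP4 responses unchanged. It acts there through the estimated spread alone, so calls gained with the block are no separate support. RNA quality, scan dates and hybridisation batches were not analysed here.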

Results

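The series measured how muscle cells with and without MuSK respond to bone morphogenetic protein 4 (BMP4). MuSK is a receptor tyrosine kinase of the neuromuscular synapse, and the design addresses whether it shapes BMP responses and whether the stage of the cells matters. The cells were a wild-type and a MuSK-null mouse line, each immortalised by a temperature-sensitive large T antigen. Myoblasts were kept at 33 °C, and myotubes were differentiated for 3 days at 37 °C. Cells were left untreated or received 25 ng/ml BMP4 for 8 h, with 3 arrays in each of the 8 groups. Treated myoblasts were deprived of serum for 4 h beforehand. The labels do not say whether untreated myoblasts were, so serum and BMP4 may be mixed in the myoblast contrasts. For all myotubes the labels give 0 h of deprivation, so serum may also enter the stage and three-way differences of responses. Each genotype is represented by 1 cell line, so a genotype contrast is also a contrast of lines. The first principal component carried 54.9% of the variance and the second 21.4%.

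Musk itself was measured by 1 probe set (10505145). Its signal was 11.57 ± 0.07 (SD, n = 3) in untreated wild-type myoblasts and 10.85 ± 0.14 (SD, n = 3) in untreated MuSK-null myoblasts, a fall by 0.72 log2 units (SE 0.07, adjusted p = 2.81e-08). In untreated myotubes the signal was 12.72 ± 0.04 (SD, n = 3) in wild type and 11.22 ± 0.04 (SD, n = 3) in MuSK-null cells, a difference of -1.51 (SE 0.07, adjusted p = 5.68e-14). Which exons were deleted is not given in the sources used here, so the signal left in the MuSK-null arrays may come from exons that remain and the probe set checks the labels only in part. BMP4 raised Musk by 0.56 (SE 0.07, adjusted p = 4.26e-06) in wild-type myoblasts. The change was 0.19 (SE 0.07, adjusted p = 0.128) in MuSK-null myoblasts, where it passed the threshold with the array set as a block (adjusted p = 0.0408).

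**Figure D1:**
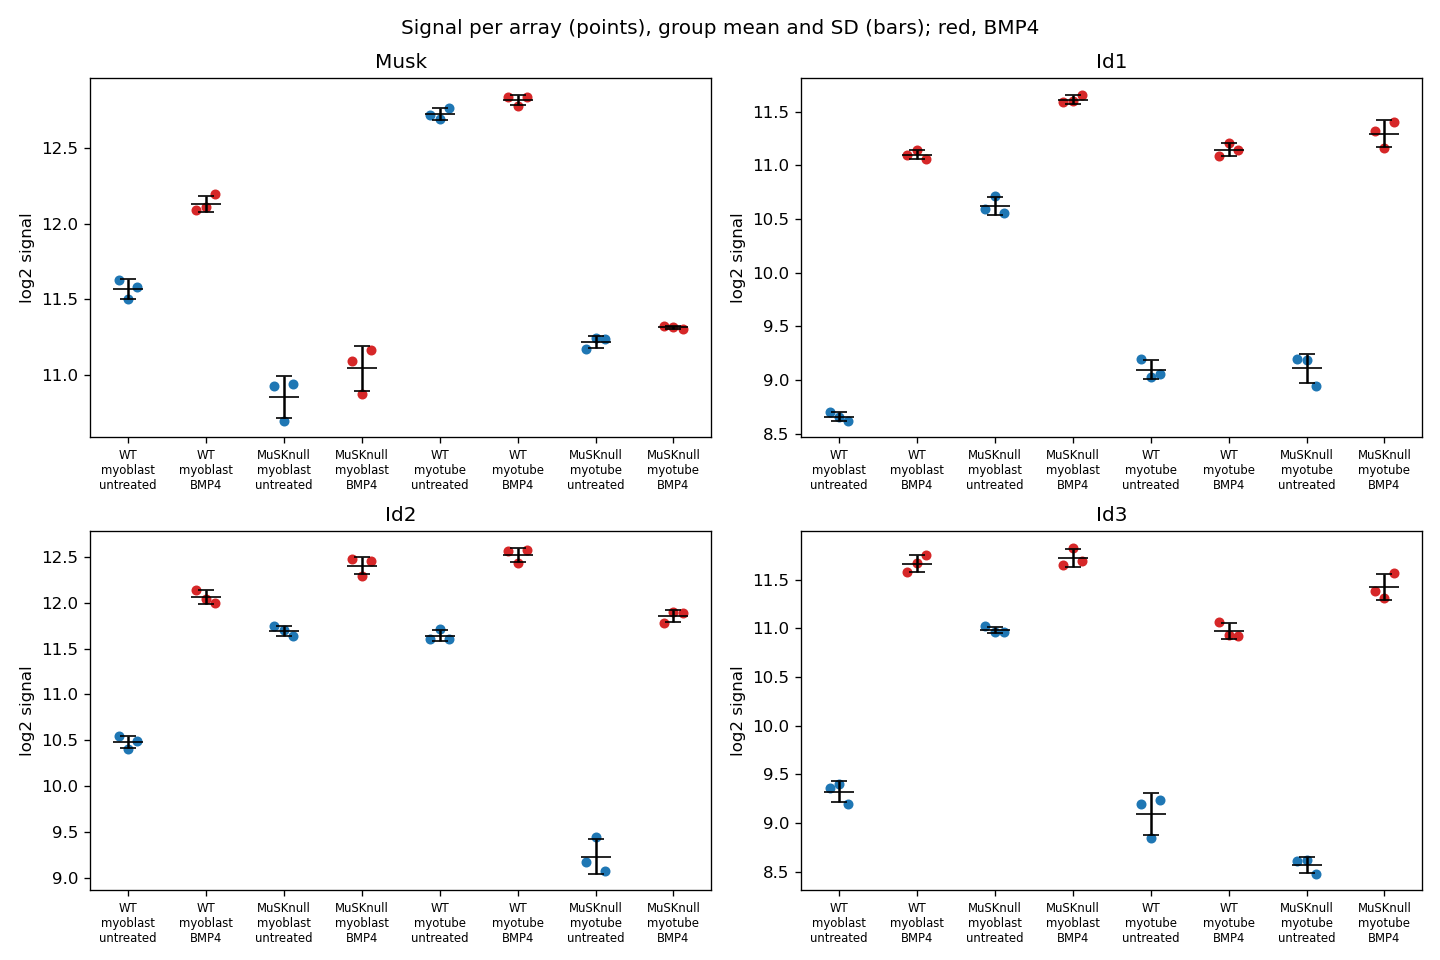
Log2 signal of Musk, Id1, Id2 and Id3 on each of the 24 arrays, with points for arrays and bars for the group mean and SD (n = 3), BMP4-treated groups in red. Untreated Id1 lies near 8.66 in wild-type and 10.62 in MuSK-null myoblasts, while the treated groups lie at 11.10 and 11.61.

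In wild-type myoblasts BMP4 raised the canonical BMP response genes. Id1, Id3 and Id2, inhibitors of basic helix-loop-helix factors, rose by 2.44 (SE 0.07), 2.35 (SE 0.09) and 1.58 (SE 0.08) log2 units. The inhibitory Smads Smad6 and Smad7 rose by 2.29 and 1.86. Sp7, a transcription factor of osteoblasts, rose by 3.40 (SE 0.14, adjusted p = 3.85e-14), and Alpl, an alkaline phosphatase of bone, by 2.13. Fabp7, a fatty acid binding protein, rose by 3.18 and Rgs4, a regulator of G-protein signalling, by 2.51. Of 29 measured BMP and Smad target genes 24 rose and 0 fell (26 and 0 adjusted over the list alone; adjusted p = 1.04e-06 with an estimated correlation). Of 18 osteoblast differentiation genes 7 rose (7 rose and 3 fell adjusted over the list alone; adjusted p = 0.000534 with an estimated correlation). Of 42 sarcomere genes 16 fell (24 adjusted over the list alone), among them Mybph by -0.67 and Myom2 by -0.56, and the list's adjusted p was 0.00172 with an estimated correlation. Of 17 genes of myoblast fusion and membrane 11 fell and 1 rose (12 and 1 adjusted over the list alone; adjusted p = 0.00673 with an estimated correlation). The acetylcholine receptor subunit genes Chrnd and Chrng fell by 0.90 and 0.76, but the neuromuscular list as a whole (9 of 26 fell and 4 rose, the same numbers adjusted over the list alone) had an adjusted p = 0.168 with an estimated correlation. TGF-beta and matrix response genes rose in 12 of 23 cases and fell in 1 (12 and 2 adjusted over the list alone; adjusted p = 0.00723 with an estimated correlation). Wnt pathway genes rose in 16 of 46 cases and fell in 6 (18 and 6 adjusted over the list alone; adjusted p = 0.0233 with an estimated correlation), and immediate early genes rose in 10 of 24 with 0 falls (11 and 0 adjusted over the list alone; adjusted p = 0.0233 with an estimated correlation). Hox and positional genes rose in 13 of 42 cases and fell in 2 (14 and 2 adjusted over the list alone; adjusted p = 0.0419 with an estimated correlation). Medag (-2.06), Lrig1 (-1.76), Bnc2 (-1.74) and Mest (-1.73) were among the large falls. In all, 1038 genes were higher and 1148 lower of 19938; with the array set as a block 2768 genes were called, and without the set 1923.

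In MuSK-null myoblasts the same target list rose, 24 of 29 genes with 0 falls (the same adjusted over the list alone; adjusted p = 5.37e-06 with an estimated correlation). The rise of Fabp7 was 3.43 (SE 0.08), that of Smad6 1.99 and that of Smad7 1.40. Id1 rose by 0.99 (SE 0.07), Id3 by 0.74 (SE 0.09) and Id2 by 0.71 (SE 0.08). Sp7 rose by 1.74 and Rgs4 by 0.63. Lin7a (2.31), Lgr6 (2.20) and Trabd2b (2.08) were among the other large rises. Chrnd fell by 1.92 and Chrng by 1.31, and 9 of 26 neuromuscular genes fell with 0 rises (10 and 3 adjusted over the list alone; adjusted p = 0.0137 with an estimated correlation). Myog, a myogenic transcription factor, fell by 0.67, and 5 of 19 myogenic regulators fell (8 adjusted over the list alone; adjusted p = 0.0429 with an estimated correlation). Of 42 sarcomere genes 15 fell and 2 rose (21 and 3 adjusted over the list alone; adjusted p = 0.00482 with an estimated correlation). In all, 776 genes were higher and 902 lower; with the compared groups alone in the fit 1115 genes were called. The balance of directions depends on the scaling: with arrays centred on their median 33.9% of 1648 called genes were higher. Both genotypes shared 462 higher genes, against 40.4 for independent lists, and 574 lower genes, against 51.9, while 29 genes were called in opposite directions.

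The difference between the myoblast responses was called for 477 genes, 233 with a higher and 244 with a lower response in MuSK-null cells. With arrays centred on their median 36.7% of 447 called genes had a higher response. Id1, Id2 and Id3 responded less, with differences of -1.60 for Id3 (SE 0.13, adjusted p = 5.08e-08), -1.45 for Id1 (SE 0.10, adjusted p = 1.06e-08) and -0.87 for Id2 (SE 0.11, adjusted p = 4.48e-05). Id4, a family member named here after its values were seen, differed by -0.14 (adjusted p = 0.865). Rgs4 (-1.88), Sp7 (-1.67) and Ptgs2, a prostaglandin synthase (-1.63), also responded less. After BMP4, Id1 was higher in MuSK-null myoblasts (11.59 to 11.66, against 11.06 to 11.15 in wild type). So was Ptgs2 (12.83 to 13.02, against 12.67 to 12.79), which was also higher untreated (12.13 to 12.28, against 10.21 to 10.44). Treated Id2 was higher too, and treated Id3 overlapped. The smaller responses of these genes are therefore not lower treated levels. Treated Rgs4 was lower (7.45 to 7.67, against 8.89 to 9.09). Hpgd, which inactivates prostaglandins, differed by -2.35, and its level fell by 1.74 in MuSK-null cells. Lin7a (1.90) and Tgm2, a transglutaminase (1.67), had higher responses in MuSK-null cells. Smad6 differed by -0.30 (SE 0.11, adjusted p = 0.236) and Fabp7 by 0.25 (SE 0.12, adjusted p = 0.445), and neither passed the test. Smad7 (-0.46, adjusted p = 0.0498) was at the threshold. It passed with the array set as a block (adjusted p = 0.0335). The call was lost without the set (adjusted p = 0.145) and on leaving out 11 of 12 arrays in turn (adjusted p from 0.0398 to 0.149). Musk differed by -0.37 (adjusted p = 0.057), and passed with the array set as a block (adjusted p = 0.0116) but not without the set (-0.30, adjusted p = 0.0653). Of 29 BMP and Smad targets 10 had a lower and 2 a higher response (13 and 3 adjusted over the list alone; adjusted p = 0.00678 with an estimated correlation). Of 18 osteoblast genes 4 had a lower response (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.00271 with an estimated correlation), and of 26 neuromuscular genes 5 (10 lower and 3 higher adjusted over the list alone; adjusted p = 0.0434 with an estimated correlation). Of the 477 genes, 82 rose and 105 fell in wild type alone by their calls, 54 rose and 54 fell in MuSK-null cells alone, 92 changed the same way in both with a larger change in wild type and 52 with a larger change in MuSK-null cells. With the array set as a block 745 genes were called, and without the set 352.

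**Figure D2:**
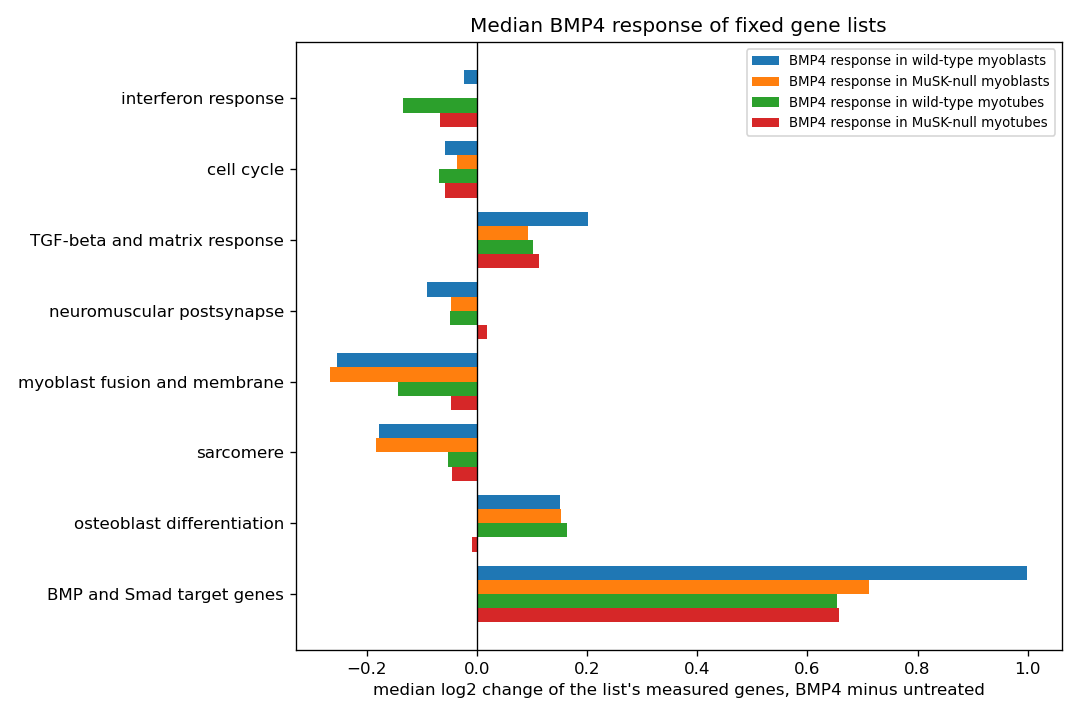
Median log2 change, BMP4 minus untreated, over the measured genes of 8 gene lists fixed beforehand, with 1 bar for each genotype and stage. The medians of the BMP and Smad target genes are 1.00 and 0.71 in wild-type and MuSK-null myoblasts, and 0.65 and 0.66 in the myotubes.

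In wild-type myotubes 20 of 29 BMP and Smad targets rose and 1 fell (21 and 1 adjusted over the list alone; adjusted p = 5.12e-06 with an estimated correlation). Fabp7 rose by 4.32 (SE 0.08), Sp7 by 3.12, Cxcr4, a chemokine receptor, by 2.12, Id1 by 2.05, Id3 by 1.88 and Id2 by 0.88. Myh15, a slow-type myosin heavy chain, rose by 1.53 (SE 0.08, adjusted p = 2.14e-11), and Wnt11 by 1.02. Osteoblast genes rose in 5 of 18 cases with 1 fall (6 and 1 adjusted over the list alone; adjusted p = 0.00282 with an estimated correlation). Falls included Fgf9 (-1.91), Mir1a-2 (-1.56), E2f2 (-1.53) and Mest (-1.51). The sarcomere list, with 4 falls and 1 rise among 42 genes, had an adjusted p = 0.117 with an estimated correlation. In all, 878 genes were higher and 871 lower.

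In MuSK-null myotubes 24 of 29 targets rose (24 rose and 1 fell adjusted over the list alone; adjusted p = 4.47e-06 with an estimated correlation). Fabp7 rose by 4.01, Id3 by 2.86, Id2 by 2.63 and Id1 by 2.19. Prr9 (2.77), Mettl21c (2.04) and Palmd (2.04) were among the largest rises, and Lum, which encodes the matrix protein lumican, was among the large falls (-1.81). Rgs4 rose by 0.49 (SE 0.09, adjusted p = 0.000426). Myh15 changed by -0.03 (adjusted p = 0.895). Immediate early genes rose in 11 of 24 cases with 0 falls (14 and 1 adjusted over the list alone; adjusted p = 0.0257 with an estimated correlation). In all, 1068 genes were higher and 1177 lower. The 2 genotypes shared 453 higher genes (47.0 for independent lists) and 463 lower genes (51.4) in myotubes.

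The difference between the myotube responses was called for 640 genes, 300 with a higher and 340 with a lower response in MuSK-null cells. Id2 (1.75, SE 0.11, adjusted p = 3.46e-09) and Id3 (0.97, SE 0.13, adjusted p = 4.67e-05) responded more in MuSK-null myotubes, opposite to their direction in myoblasts. Untreated Id2 was lower in MuSK-null myotubes (9.07 to 9.44, against 11.60 to 11.72 in wild type). It stayed lower after BMP4 (11.78 to 11.90, against 12.44 to 12.58), so its larger response is not a higher treated level. Id3 was lower untreated (8.48 to 8.62, against 8.84 to 9.24) and higher after BMP4 (11.32 to 11.57, against 10.92 to 11.06). Id1 differed by 0.14 (SE 0.10, adjusted p = 0.623). Sp7 (-2.67), Rgs2 (-1.78) and Rgs4 (-1.09) responded less. Myh15 differed by -1.56, but its signal was 4.78 to 4.98 on the MuSK-null myotube arrays and 4.77 to 5.02 on the myoblast arrays, so the probe set may be at background there and the size of its difference cannot be read. Wnt11 had a lower response (-0.60, adjusted p = 0.027), a call lost on leaving out 6 of 12 arrays in turn (adjusted p from 0.00974 to 0.0967). Fgf9 differed by 1.86 and Mettl21c by 2.04. Osteoblast genes had a lower response in 4 of 18 cases (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.00622 with an estimated correlation), and RGS and G-protein regulators in 2 of 13 (5 adjusted over the list alone; adjusted p = 0.0356 with an estimated correlation). Heat shock and stress genes had a higher response in 2 of 17 cases (4 adjusted over the list alone; adjusted p = 0.0356 with an estimated correlation). Of the BMP and Smad targets 5 had a higher and 2 a lower response (5 and 6 adjusted over the list alone), and the list had an adjusted p = 0.334 with an estimated correlation.

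Stage was compared in wild-type cells, where 682 responses differed between myotubes and myoblasts, 382 higher and 300 lower in myotubes; 1028 were called with the array set as a block and 681 without the set. Tgm2 (2.04) and Cxcr4 (1.46) responded more in myotubes. Msx2, a homeobox factor of the BMP response (-1.90), Foxq1 (-1.74) and Ptgs2 (-1.26) responded less. BMP and Smad targets responded less in 11 of 29 cases and more in 1 (12 and 1 adjusted over the list alone, adjusted p = 0.0296 with an estimated correlation). Treated myoblasts were deprived of serum and myotubes were not, and the stages differed in temperature. Stage cannot be told apart from these in the differences of responses. Id1 (-0.39, adjusted p = 0.0373) and Id3 (-0.46, adjusted p = 0.0483) were near the threshold, and leaving out 1 array in turn ended the call for 9 and 8 of 12 arrays. The stages shared 466 higher genes (45.7 for independent lists) and 471 lower genes (50.1) in wild type. In MuSK-null cells the stages shared 350 higher and 360 lower genes (41.6 and 53.2 for independent lists), and 104 were called in opposite directions. The three-way difference, which asks whether the effect of genotype on the response changes with stage, was called for 498 genes (783 with the array set as a block and 488 without the set). It was 2.61 for Id2, 2.58 for Id3 and 1.58 for Id1, and -0.25 for Id4 (adjusted p = 0.67). Differences in untreated levels between the lines enter these values, as for Id2 in myotubes.

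Some BMP targets differed between untreated myoblasts of the lines. In MuSK-null cells Id1 was higher by 1.96 (SE 0.07, adjusted p = 6.9e-16), Id3 by 1.66 and Id2 by 1.22, and the ligand gene Bmp4 by 1.64 (SE 0.11). Of 29 targets 14 were higher and 4 lower, among these Hey1 (-2.12) and Fst (-1.71) (15 and 5 adjusted over the list alone), and the list did not pass, with an adjusted p = 0.141 with an estimated correlation. Sarcomere genes were lower in 35 of 42 cases with 0 higher (37 adjusted over the list alone; median -1.95, adjusted p = 5.8e-07 with an estimated correlation), including Myh1 (-4.11), Actn2 (-3.73) and Myh3 (-3.61). Fibroblast markers were higher in 6 of 11 cases and lower in 2 (the same adjusted over the list alone; adjusted p = 0.14 with an estimated correlation), with Dcn, which encodes a matrix proteoglycan, at 2.30. The collagen gene Col1a1 was higher by 1.52. Muscle calcium handling genes were lower in 23 of 36 cases and higher in 6 (the same adjusted over the list alone; adjusted p = 0.000904 with an estimated correlation). Smooth muscle markers were lower in 6 of 10 and higher in 1 (the same adjusted over the list alone; adjusted p = 0.0139 with an estimated correlation), and Hox and positional genes were higher in 25 of 42 and lower in 1 (26 and 2 adjusted over the list alone; adjusted p = 0.0322 with an estimated correlation). The lines differed in the X-inactivation transcript Xist (7.21) and in the Y-linked genes Eif2s3y (-5.98) and Uty (-4.50). The mean signals of Eif2s3y (4.65) and Uty (4.73) in MuSK-null myoblasts and of Xist in wild-type myoblasts (5.94) may be at background, so the sizes of these differences cannot be read. Their directions are those of a female MuSK-null and a male wild-type line, so sex of the lines may also enter each genotype contrast. Grb10, an imprinted growth regulator, was higher by 5.95. In all, 3058 genes were higher and 3187 lower; 7109 were called with the array set as a block and 5870 without the set.

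Between untreated myotubes of the lines, Id1 differed by 0.01 (SE 0.07, adjusted p = 0.916), while Id2 differed by -2.42 and Id3 by -0.52 in MuSK-null cells. Bmp4 was higher by 1.78, and the ligand gene Bmp2 and the BMP antagonist gene Grem1 were lower, with differences of -3.10 and -2.97. The mean signal of Bmp2 in MuSK-null myotubes (5.93) may be at background, so the size of its difference cannot be read. Interferon response genes were lower in 20 of 27 cases and higher in 2 (21 and 3 adjusted over the list alone; median -1.01, adjusted p = 0.00136 with an estimated correlation), with Usp18 at -3.52 and Ifit1 at -3.42. Sarcomere genes were lower in 28 of 42 cases and higher in 3 (30 and 3 adjusted over the list alone; median -0.29, adjusted p = 0.0058 with an estimated correlation). Cell cycle genes were higher in 22 of 34 cases, a call lost with an estimated correlation (adjusted p = 0.3). Alox5, a lipoxygenase, differed by -5.14. Fibroblast markers were higher in 6 of 11 cases and lower in 2 (adjusted p = 0.0678 with an estimated correlation). In all, 3863 genes were higher and 3586 lower; with arrays centred on their median 45.5% of 7129 called genes were higher.

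Differentiation was compared in untreated cells. Myotubes and myoblasts also differed in culture temperature, and the large T antigen of both lines is temperature-sensitive. Differentiation can therefore not be told apart from temperature in the changes below, those of the cell cycle genes included. In wild type 42 of 42 sarcomere genes rose (the same adjusted over the list alone; median 1.83, adjusted p = 1.93e-06 with an estimated correlation) and 34 of 34 cell cycle genes fell (median -2.06, adjusted p = 0.00305 with an estimated correlation). In MuSK-null cells 40 sarcomere genes rose (41 adjusted over the list alone; median 3.39, adjusted p = 2.66e-07) and 34 cell cycle genes fell (median -1.28, adjusted p = 0.00963), both with an estimated correlation. Casq1, the calcium store protein of the sarcoplasmic reticulum, rose by 5.78 in wild type and 6.02 in MuSK-null cells. Musk rose by 1.15 (SE 0.07, adjusted p = 3.66e-12) and by 0.36 (SE 0.07, adjusted p = 0.000193). Id1 rose by 0.44 in wild type and fell by 1.51 in MuSK-null cells. The counts were 4048 higher and 4918 lower in wild type, and 3623 higher and 4664 lower in MuSK-null cells; with the array set as a block 9450 and 8838 genes were called. The changes differed between the lines for 5796 genes (6775 with the set as a block, 5867 without it). The change was higher in MuSK-null cells for 32 of 42 sarcomere genes and lower for 5 (33 and 6 adjusted over the list alone, adjusted p = 4.19e-05 with an estimated correlation). Most sarcomere genes were lower in untreated MuSK-null myoblasts, as given above, and most were still lower in the myotubes. Their larger rise is therefore not a higher level in MuSK-null myotubes. For interferon genes the change was lower in 17 of 27 cases and higher in 1 (18 and 3 adjusted over the list alone, adjusted p = 0.00348 with an estimated correlation).

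**Figure D3:**
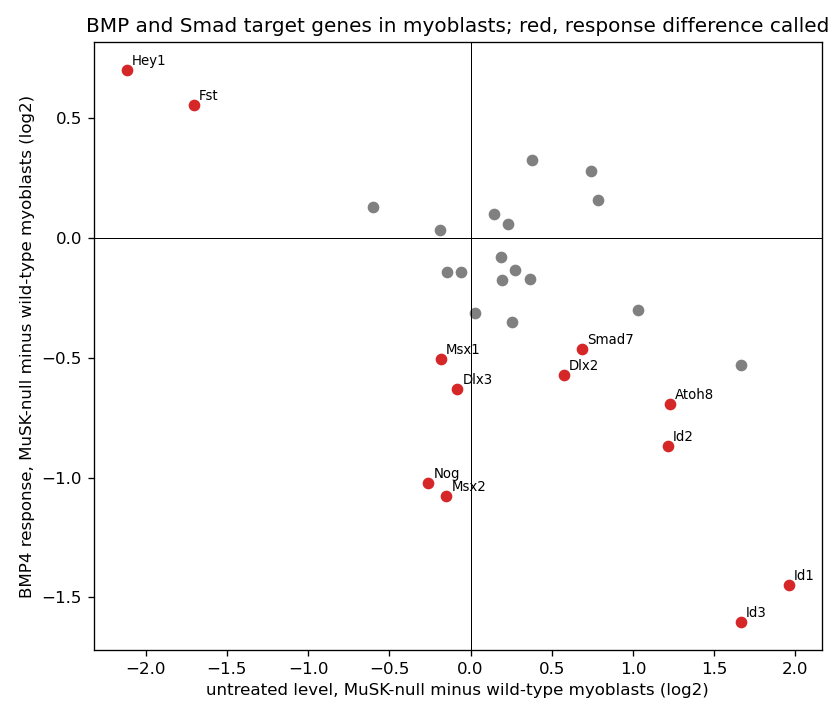
Each point is 1 of 29 BMP and Smad target genes in myoblasts; the horizontal axis gives the untreated MuSK-null minus wild-type level and the vertical axis the MuSK-null minus wild-type difference of BMP4 responses, both in log2 units, with called response differences in red. Id1 lies at 1.96 and -1.45, and the correlation across these genes, which are not independent replicates, is -0.63. The untreated difference enters both axes with opposite sign, so a negative correlation is partly built in.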

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

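The test of the Bmp4 transcript and the regroupings of arrays were chosen only after the results were seen. Single arrays were not tested as outliers within their groups of 3.

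BMP4 responses that differed between groups were picked out by an interaction test. The numbers of genes were 477 between genotypes in myoblasts, 640 between genotypes in myotubes, 682 between stages in wild type and 498 in the three-way difference, and 5796 genes differed in their change on differentiation. Arrays were regrouped in 2 ways, 100 splits each, first by shuffling treatment or stage labels within a genotype and stage and, once those counts were known, by regrouping freely. Both are given here. For the difference in myoblasts 12 of 100 splits of the first kind gave as many genes (highest other 1458) and 8 of the second (highest other 4018). For the difference in myotubes 5 of 100 (highest other 1250) and 12 of 100 (highest other 4827) gave as many as 640. For the change on differentiation 9 of 100 (highest other 6301) gave as many as 5796, and 1 of 100, the real split, when regrouped freely (highest other 5537). For the stages in wild type the numbers were 9 of 100 (highest other 2928) and 4 of 100 (highest other 6370). For the three-way difference they were 3 of 100 (highest other 627) and 2 of 100 (highest other 1003). Some splits called more genes than the real one. In the first kind the split with most genes swapped 4 of 12 labels in myoblasts and 8 of 12 in myotubes. It swapped 8 of 12 for the change on differentiation, 6 of 12 for the stages and 10 of 24 for the three-way difference. Partly swapped labels let the BMP4 response, or the change on differentiation, enter the difference, and free regrouping lets genotype or stage enter too. The median of the other splits was 0 genes in the first kind. Splits that carry such real effects are no measure of chance, so for these 5 results the splits decide nothing about chance in either direction.

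For the remaining contrasts 3 arrays against 3 make 10 splits, too few for a share under 0.05; in each, 1 split, the real one, reached the real number. The real numbers and the highest of the others were 2186 and 0 for BMP4 in wild-type myoblasts, 1678 and 2 in MuSK-null myoblasts, 1749 and 0 in wild-type myotubes, 2245 and 0 in MuSK-null myotubes, 6245 and 0 for genotype in myoblasts, 7449 and 0 in myotubes, and 8966 and 0 for differentiation in wild type and 8287 and 0 in MuSK-null cells. For BMP4 in MuSK-null myoblasts and for genotype in myoblasts, where same-numbered arrays deviated together, this holds for the splits that part as many pairs as the real one and for the rest.

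Among the genes named in every comparison, the response differed between genotypes in myoblasts for Id1 (-1.45), Id2 (-0.87), Id3 (-1.60), Smad7 (-0.46), Rgs4 (-1.88) and Ptgs2 (-1.63), and in myotubes for Id2 (1.75), Id3 (0.97), Rgs4 (-1.09), Wnt11 (-0.60) and Myh15 (-1.56). Between stages in wild type it differed for Musk (-0.47), Id1 (-0.39), Id2 (-0.70), Id3 (-0.46), Smad6 (-0.51), Rgs4 (-0.92), Wnt11 (0.73), Myh15 (1.46), Ptgs2 (-1.26) and Fabp7 (1.14). In the three-way difference it differed for Id1 (1.58), Id2 (2.61), Id3 (2.58), Smad7 (0.74), Rgs4 (0.78), Myh15 (-1.43) and Ptgs2 (1.30). The change on differentiation differed for Musk (-0.79), Id1 (-1.95), Id2 (-3.63), Id3 (-2.19), Smad6 (-0.74), Smad7 (-0.95), Rgs4 (-0.47), Car3 (-0.36), Wnt11 (0.57), Myh15 (-0.78) and Ptgs2 (-1.75). All are log2 differences with adjusted p under the threshold in limma. Myh15 lay at 4.77 to 5.02 on the myoblast arrays and 4.78 to 4.98 on the MuSK-null myotube arrays, so the sizes of its differences cannot be read.

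Gene lists that differed are given by their adjusted p with an estimated correlation. In the myoblast difference these were BMP and Smad targets (0.00678), osteoblast genes (0.00271), the neuromuscular list (0.0434) and the 6 prior candidate genes (0.00271), all lower in MuSK-null cells. In the myotube difference they were osteoblast genes (0.00622), RGS genes (0.0356) and the prior candidates (0.00279), lower, and heat shock genes (0.0356), higher. The prior candidates (Rgs4, Car3, Wnt11, Myh15, Ptgs2 and Fabp7) were fixed beforehand without a recorded source, so their direction is not counted as independent evidence. On differentiation they were sarcomere (4.19e-05) and interferon genes (0.00348), and between stages in wild type BMP and Smad targets (0.0296). In the three-way difference they were BMP and Smad targets (0.0285), the neuromuscular list (0.0406), immediate early genes (0.0495) and heat shock genes (0.0406).

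Rows without a single gene name, which no comparison used, also responded to BMP4: of 13767 such rows 86 were called in wild-type myoblasts, 64 in MuSK-null myoblasts, 87 in wild-type myotubes and 99 in MuSK-null myotubes.

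Over the 29 targets, a higher untreated level in MuSK-null myoblasts went with a smaller response (r = -0.63), although Msx1, Dlx3, Nog and Msx2 had smaller responses without a higher untreated level. Conversely, Smad9, Gata2 and Grem1 had higher untreated levels (0.78, 0.74 and 0.38) without a smaller response (differences of 0.16, 0.28 and 0.33, not called). The smaller responses of Gata3 and Smad6 were not called. Untreated arrays enter both quantities. Their chance spread gives 2.63% of the observed covariance (-0.01 against -0.30), which argues against array noise alone as the cause. However, the untreated difference enters the response difference with the opposite sign. A negative correlation is therefore partly built in for real differences too, and r is no separate evidence of a smaller response. A signal ceiling common to all probe sets is also argued against. When treated, 0 of the 10 targets with a smaller response lie above the 99th percentile of genes (12.8), the highest being at 12.4. A plateau of single probe sets or of the induction itself was not tested, since either could lie below that level. Higher Bmp4 transcript alone stays open: of 14 targets higher in untreated MuSK-null myoblasts 4 are higher in MuSK-null myotubes too, where Bmp4 is also higher, but 11 of the 29 targets are lower there, with Id2 at -2.42 and Id3 at -0.52, and so are Bmp2 and Grem1. An effect of genotype was not tested apart from other traits of this line, since there is 1 line per genotype.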

How the results depend on the processing

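The fits with the array set as a block and without it, and list tests with centred arrays or the array set, were chosen only after the data were seen; the rest were planned. Over all alternatives no named gene that was called in the main or the alternative fit changed direction. Many of them could not change one. The compared groups alone, trend and robust estimation, the filter, single rows, the fold change and replicate blocks keep the same group means. Only the scalings, the arrays left out and the fits with or without the array set could reverse a direction. Named genes called in neither fit were not checked for direction, and counts were compared by size alone. Centring the arrays moved the share of higher genes to 33.9% for BMP4 in MuSK-null myoblasts and to 36.7% for the myoblast difference. It moved the share to 45.5% for genotype in myotubes and to 59.4% for the three-way difference. With a fold change of at least 1.5 the counts fell to 552, 418, 356 and 546 for BMP4 in wild-type and MuSK-null myoblasts and wild-type and MuSK-null myotubes, to 236 and 281 for the differences between genotypes in myoblasts and myotubes, to 1821 and 2297 for genotype, to 3560 and 3279 for differentiation, to 2567 for its difference and to 280 for stages in wild type, because the threshold is stricter. Genes shared in both directions, higher and lower, fell to 118 and 118 between myoblast genotypes, 102 and 75 between myotube genotypes, 115 and 69 between wild-type stages and 73 and 58 between MuSK-null stages. With only the compared groups in the fit, BMP4 in MuSK-null myoblasts called 1115 genes, the lower genes shared by both genotypes were 375, and those shared by MuSK-null stages were 233 higher and 238 lower; the cause was not tested. With the array set as a block the counts rose to 745, 1028 and 783 for the myoblast difference, the stages in wild type and the three-way difference. The block leaves these estimates unchanged, so the rise comes from a smaller estimated spread. The set was picked from deviations of these same arrays, so the rise is no separate support.

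Leaving out 1 array at a time gave 1808 to 1956 and 1332 to 1655 genes for BMP4 in wild-type and MuSK-null myoblasts, 1333 to 1637 and 1759 to 2068 in the myotubes, 371 to 449 and 473 to 617 for the genotype differences, 5527 to 5829 and 6547 to 6887 for genotype, 8203 to 8591 and 7629 to 7879 for differentiation, 5228 to 5607 for its difference, 536 to 640 for stages and 389 to 501 for the three-way difference. Smad7 in the myoblast difference lost its call for 11 of 12 arrays left out, Wnt11 in the myotube difference for 6 of 12, and Id1 and Id3 between wild-type stages for 9 and 8 of 12.

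Replicate numbers do not pair the samples over all groups: 24 of 84 same-number pairs had a correlation of deviations above 0.1 (range -0.36 to 0.52), and 8 of 24 arrays matched their own number best. They do so among untreated wild-type, untreated MuSK-null and treated MuSK-null myoblasts, where the pairing cannot be told apart from membership in the array set. With the replicate block 2213, 1715, 1778 and 2275 genes were called for the 4 BMP4 responses and 462 and 638 for the genotype differences, and 6300 for genotype in myoblasts. With the block within genotype and stage, which leaves fewer degrees of freedom, 1957, 1469, 1551 and 1984 genes were called for the BMP4 responses, 359 and 463 for the genotype differences (70.9% and 68.8% of the calls kept), 549 for stages in wild type (75.7% kept) and 374 for the three-way difference (69.7% kept).

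With fry, 2 lists not called before had the opposite sign, TGF-beta and matrix genes between untreated myotubes (adjusted p = 0.00308) and RGS genes on differentiation in wild type (adjusted p = 0.0388); the cause was not tested. With an estimated correlation 69 of 351 list results lost their call. The 3 arrays per group limit what can be called, as do probe sets near background.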

Other observations

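The tests below were chosen after the results were seen, except those of the segment, of brightness and of dose, whose predictions came first.

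Cdkn2a and Cdkn2b, which encode cell cycle inhibitors, and their neighbour Mtap were much lower in the MuSK-null line. Mtap was named by the rule; Cdkn2a and Cdkn2b were chosen after their values were seen. In untreated myoblasts the differences were -4.21 for Mtap, -3.43 for Cdkn2a and -2.88 for Cdkn2b, and in myotubes -3.97, -2.68 and -3.45. The mean signal of Mtap over the MuSK-null arrays (6.07) may be at background, so the size of its differences cannot be read. The next gene in the RefSeq order (assembly GRCm38.p6), Dmrta1, was higher by 2.53 in myoblasts. On the side of Mtap, Mir31 differed by -0.46. With Xist and Eif2s3y, 0 of 24 arrays lay on the side of the other genotype, which argues against mislabelled arrays as the source. A lost chromosome segment would leave the 3 genes at background; the highest of their MuSK-null means was at percentile 43.3 of gene means, which decides neither way. Loss, silencing and an effect of genotype cannot be told apart with 1 line per genotype.

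Genes on chromosome 16 were lower in MuSK-null than in wild-type myotubes, with a median of -0.29 log2 units over 371 genes above the median row, against -0.13 to 0.12 for the other chromosomes. In myoblasts the median was -0.03, against -0.19 to 0.10 for the other chromosomes. Of these, chromosome 4, which carries Cdkn2a, Cdkn2b and Mtap, was lowest in myoblasts (-0.19, 710 genes) and in myotubes (-0.13). The cause of the chromosome 4 shift was not tested. The chromosome 16 shift lies in the wild-type myotubes: their 6 arrays were 0.19 to 0.23 above the other chromosomes and the other 18 arrays -0.09 to -0.04. Scaling by brightness is argued against, because chromosome 16 lay at percentile 0 of 10000 brightness-matched random gene sets. Their medians ran from -0.05 to 0.10. Other chromosomes also lay outside that range, among them 4 (-0.13) and 18 (0.12), so it does not measure the usual spread between chromosomes. A first test of a differentiation change common to both lines assumed a shift in MuSK-null cells and so could not decide. Its replacement was written after the values were seen. It gave shifts of chromosome 16 on differentiation of 0.27 in wild type and 0.02 in MuSK-null cells. The difference of 0.25 (bootstrap SD 0.03) argues against a common change. A candidate explanation is a higher dose of the whole of chromosome 16 in the wild-type cultures that became myotubes: 5 of 5 blocks of its genes in chromosome order were shifted by over 0.1. DNA copy number was not analysed here, and the hypothesis rests on the data it was found in.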
